A study of Homo sapiens with 6 samples.

How the data were processed

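RNA from THP-1 cells of 3 groups was measured on 6 single-colour arrays, with 2 arrays for each of resting, LPS, and LC53 plus LPS cells. Per the labels, total RNA was amplified with an amino allyl kit and labelled with Cy5 dye, and the cells were kept in medium with 0.5% serum. The labels did not say whether the 2 arrays of a group came from separate cultures. The deposited values were linear probe intensity. On each array every value was a whole number times 1 factor of that array, within a tolerance of 0.02. A linear scaling by the authors was thus seen, and no quantile or loess step. The factors were 0.992 and 1.01 on the resting arrays, 1.04 and 0.962 on the LPS arrays, and 0.906 and 1.12 on the LC53 plus LPS arrays. In each group they lay on either side of 1, as from a scaling within the group. A common scale for the 3 groups was not shown. The scanner, background correction and normalization method were not given in the sources used here.

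All 31741 probes had a value on every array and entered the tests. Values under 1 were set to 1 and log2 was taken. The arrays were used as deposited, although their log2 medians differed by up to 0.556, with LPS replicate 2 above LPS replicate 1. Probes at or above 65500 whole-number units were counted as saturated, which was the case for 96 probes on at least 1 array and for 33 on all arrays. Differences were read as lower bounds where only the higher group was saturated. Where both groups held saturated arrays, differences were not read as a measure of change. Log2 differences of probes near 0 depend on the value of 1 set before the log, so intensities, or differences with an offset of 50, were given for these.

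Probes were matched to symbols through the probe table and the RefSeq gene table. A single symbol was found for 24658 probes, several for 1002 and none for 6081. Of the symbols, 22404 probes carried a current one, 2177 an updated one and 77 one kept as given. The 18255 genes were each represented by the probe with the highest mean over the 6 arrays, and 5450 genes had several probes. Other probes of called genes had the same sign in 91.7%, 87.2% and 89.1% of cases for LPS against resting, LC53 plus LPS against LPS, and LC53 plus LPS against resting.

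The model was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 6 arrays and a moderated, 2-sided test of each of the 3 contrasts. P-values were adjusted by Benjamini-Hochberg over 31741 probes and called below 0.05. Of the 2069, 834 and 941 called probes, 324, 132 and 137 had a lower group mean under 16 intensity units, and in 261, 88 and 111 both means were under 50. The groups, the tests of the 3 contrasts and of the gene lists, the lists, the named-gene rule and all alternatives except 1 were chosen before the data were examined, and tests chosen later are named as such where their results stand.

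Named genes were the 8 highest and 8 lowest log2 differences among called genes whose arrays did not overlap between groups, for LPS against resting and for LC53 plus LPS against LPS, and the 4 highest and 4 lowest for LC53 plus LPS against resting. Up to 4 called members of each gene list with the largest differences were added for the first 2 contrasts, and a panel of 14 genes was named whatever its result. Genes outside the rule are named as chosen after their values were seen.

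The 27 gene lists were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01 and with an estimated correlation. They were also tested with fry, whose directional p tests whether a list's genes move on balance one way and does not compare the list with other genes. P-values were adjusted over the 27 lists within a contrast. Counts adjusted over the list alone used Benjamini-Hochberg within the list.

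The overlap of LPS and LC53 calls was set beside the product of the call shares and beside 100 simulations of unchanged groups that shared the LPS arrays. The simulated groups held no LPS response, and their noise was drawn separately for each probe. The share of the LPS rise remaining was taken from genes chosen on one LPS array and measured on the other, and from both arrays. Among genes raised by LPS, list members and others were compared with Fisher's exact test, a test chosen after the list results were seen. It takes genes as independent, which genes regulated together and measured on the same arrays are not. Random lists matched on mean intensity numbered 10000. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

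The steps were tested on simulated data. With 100 probes changed by 1 on the log2 scale and 100 changed by 2, 0 and 63 were called, and with 50 and 50 in the second contrast 0 and 28. False calls numbered 6 and 1, with 0 in the wrong direction. Few of the 31741 simulated probes were changed, while 2069 and 834 were called in the data for these 2 contrasts. The adjusted threshold is stricter when fewer probes change, so the shares recovered do not measure the sensitivity in the data. A list shifted in the simulation had a camera adjusted p of 1.84e-37 and 0 other lists were called.

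The alternatives were quantile normalization, median centring and cyclic loess, leaving out dim probes, a variance trend, fitting only the 4 arrays compared, a replicate block, array weights, each array left out in turn, an offset of 50, the mean of a gene's probes, other thresholds, and leaving out saturated probes, which was added after the saturation was seen. Other splits of the samples were not counted, since each group held 2 arrays.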

Results

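RNA of THP-1 cells, an established human monocytic leukaemia line, was measured on 6 single-colour Cy5 arrays with 31741 probes each. The arrays fell into 3 groups of 2. Resting cells received neither agent. LPS cells received 50 ng/ml lipopolysaccharide, the bacterial outer membrane component sensed by TLR4, for 8 h. LC53 plus LPS cells received 5 µM of the compound LC53 15 min before the same LPS treatment. No cells with LC53 alone were listed, so the compound's own effect could not be separated from its effect on the LPS response. The series title names theissenolactone C, TAK-1/IKK signalling and sepsis. The structure of LC53 was not given in the sources used here.

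The median probe intensity was 99.2 and 110.9 on the resting arrays, 84.4 and 124.0 on the LPS arrays, and 110.5 and 112.7 on the LC53 plus LPS arrays. Between 38 and 95 probes per array were saturated. Replicates correlated at r = 0.9931 for resting, 0.9896 for LPS and 0.9879 for LC53 plus LPS across probes, which are not independent replicates, and arrays of different groups at 0.9696 to 0.9806. The first principal component held 41.1% of the variance, with resting arrays at -65.3 and -62.1, LC53 plus LPS arrays at -0.876 and -9.22, and LPS arrays at 67.5 and 70.01. The second held 27.3%, with LC53 plus LPS arrays at -53.6 and -54.5, LPS arrays at 61.4 and -12.6, and resting arrays at 39.96 and 19.4. The number of arrays, 2 per group, limited the precision of each value. Unless stated otherwise, intensities are means ± SD with n = 2, and log2 differences are ± SE.

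The comparison of LPS with resting cells asked which genes LPS changed. LPS raised 50 of 54 interferon-stimulated genes, 25 of 31 NF-kB subunits and feedback genes, 18 of 27 chemokines and 15 of 33 inflammatory cytokines. Each list passed camera with a preset correlation, at adjusted p of 1.71e-51, 2.19e-30, 2.73e-20 and 8.59e-09, and none with an estimated correlation (adjusted p = 0.464 for the first 3 and 0.603 for cytokines). IL1B, encoding the cytokine interleukin-1 beta (probe PH_hs_0007166), rose from an intensity of 183 ± 21.3 to 38698 ± 1347 (n = 2 each), a log2 difference of 7.73 ± 0.19 (adjusted p = 0.00016). CCL2, encoding a chemokine that attracts monocytes (probe PH_hs_0015664), rose from 321 ± 0.410 to 42005 ± 3127, and CXCL8, encoding the neutrophil chemokine interleukin-8 (probe PH_hs_0000069), from 344 ± 16.1 to 27836 ± 636. TNF, encoding tumour necrosis factor, rose from 778 ± 134 to 13563 ± 266, a log2 difference of 4.13 ± 0.20 (adjusted p = 0.000519). The largest rise among the named genes was that of TNFAIP6, which encodes a hyaluronan-binding protein, from 24.98 ± 2.53 to 13983 ± 3547, a log2 difference of 9.11 ± 0.26, or 7.52 with an offset of 50.

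Of the 27 chemokines measured, 18 rose and 0 fell, and 19 rose and 1 fell when adjusted over the list alone. CXCL10, an interferon-induced chemokine, rose by 7.73 on the log2 scale and CCL20, a ligand of CCR6, by 6.46. Of 33 inflammatory cytokines, 15 rose and 2 fell, and 20 rose and 4 fell when adjusted over the list alone. IL12B, the p40 subunit shared by interleukin-12 and interleukin-23, rose from 8.51 to 2992, and IL23A, the other subunit of interleukin-23, from 746 to 35169. Of 30 genes of adhesion, co-stimulation and migration, 14 rose and 3 fell (16 and 4 adjusted over the list alone). The endothelial and monocyte adhesion molecules VCAM1 and ICAM1 rose, VCAM1 from 11.9 and 12.1 on the resting arrays to 4220.4 ± 339.8 and ICAM1 by 5.93. Of 31 NF-kB subunits and feedback genes, 25 rose and 0 fell (28 and 0 adjusted over the list alone). BCL2A1, a survival factor of the BCL2 family, rose from 10.9 and 11.1 on the resting arrays to 1533 ± 42.1, the ubiquitin ligase gene BIRC3 from 18.0 ± 3.04 to 1347 ± 85.4, IER3, an immediate early response gene, by 5.43, and TNFAIP3, encoding the deubiquitinase A20 that restrains NF-kB, by 3.60.

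Of 54 interferon-stimulated genes, 50 rose and 0 fell (52 and 0 adjusted over the list alone), with a median log2 difference of 3.11. IDO1, a tryptophan-degrading enzyme, rose from 24.5 ± 5.24 to 5442 ± 121, and IFI44L, a type I interferon target, from 205 ± 13.1 to 8808 ± 348. In the camera test with a preset correlation the adjusted p was 1.71e-51 for interferon-stimulated genes, 2.19e-30 for NF-kB genes and 2.73e-20 for chemokines (adjusted p = 0.464 with an estimated correlation for each). It was 8.59e-09 for cytokines, 1.59e-09 for adhesion genes, 5.02e-09 for the 31 genes of the AP-1, immediate early and MAPK phosphatase list and 1.08e-09 for the 31 targets of the stress-responsive factor NRF2 (adjusted p = 0.603 with an estimated correlation for each). In the AP-1 list 12 genes rose and 1 fell (17 and 2 adjusted over the list alone). Among those that rose was the transcription factor gene JUNB, by 2.66, or 1.65 with an offset of 50. Among NRF2 targets 11 rose and 0 fell (13 and 1 adjusted over the list alone), including HMOX1, the haem-degrading enzyme haem oxygenase 1, from 76.0 ± 3.74 to 953 ± 93.9, and the ferritin heavy chain gene FTH1, by 4.15.

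A further 6 lists passed camera with a preset correlation. Of 29 genes of coagulation, plasminogen and proteases, 7 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.000254). The matrix metalloproteinase genes MMP1 and MMP9 rose, MMP1 from 18.5 ± 0.928 to 464 ± 98.9 and MMP9 by 3.75. SERPINB2, encoding plasminogen activator inhibitor 2, fell from 12939.8 ± 1222 to 537 ± 24.7, a log2 difference of -4.59 ± 0.19. Of 33 genes of TLR4 to IKK and MAPK signalling 3 rose and 1 fell (6 and 2 adjusted over the list alone, 0.00716), with IRAK2 at 3.13 and MAP3K8 at 2.45, both kinases of the pathway. Of 30 apoptosis and BCL2 family genes 7 rose and 2 fell (13 and 4 adjusted over the list alone, 0.0103). Of 20 genes of cholesterol synthesis and uptake 0 rose and 2 fell (1 and 6 adjusted over the list alone, 0.00414). Among 18 MHC class I and immunoproteasome genes 2 rose (2 adjusted over the list alone, 0.0372), and of 6 metallothioneins only MT2A rose (1 adjusted over the list alone, 0.0372), a call of the gene that ended without resting replicate 1 (0.0597) or 2 (0.0600). For these 6 lists adjusted p = 0.846 with an estimated correlation. The MHC class I call ended under quantile normalization (0.0671), median centring (0.0701), cyclic loess (0.0596), without the dimmer probes (0.0545) and without resting replicate 2 (0.0797) or LPS replicate 1 (0.191). Without LPS replicate 1 the TLR4 (0.0828) and apoptosis (0.153) calls also ended. The metallothionein call ended without resting replicate 2 (0.0762) or LPS replicate 2 (0.0568), and the cholesterol call without LPS replicate 2 (0.0568).

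The other 14 lists did not pass. Members that rose and fell numbered 5 and 2 of 18 in prostaglandin and leukotriene synthesis, where PTGS2, encoding cyclooxygenase 2, rose by 3.03. The counts were 4 and 3 of 21 inflammasome and pyroptosis genes, 5 and 2 of 22 p53 targets, 4 and 1 of 34 glycolysis and hypoxia genes, 4 and 2 of 30 monocyte and macrophage identity genes, and 4 and 0 of 28 lysosome and autophagy genes. They were 1 and 3 of 34 unfolded protein and integrated stress response genes, 0 and 3 of 24 lipid efflux and scavenger receptor genes, 1 and 0 of 42 cell cycle genes, and 1 and 0 of 14 MHC class II genes. Adjusted over the list alone they were 7 and 3 for prostaglandins, 7 and 6 for the inflammasome, 5 and 2 for p53, 6 and 3 for glycolysis, 8 and 5 for monocyte identity, 5 and 0 for lysosome, 1 and 3 for unfolded protein, 4 and 7 for lipid efflux, 1 and 0 for cell cycle and 2 and 0 for MHC class II. No member passed among 26 heat shock, 36 oxidative phosphorylation and 38 ribosomal protein genes, in either count. These lists held 1, 3 and 10 members saturated on at least 1 array, whose changes may not have been measured in any contrast. Median and mean differed in sign for p53 targets (-0.00 and 0.31) and for glycolysis (-0.01 and 0.18), and the test direction was up in both. Of 29 markers of other cell types 2 rose (2 adjusted over the list alone), the fibroblast proteoglycans DCN, from 10.99 to 136, and LUM, from 75 to 311, whose call ended without resting replicate 1 (0.0654).

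Several panel genes carried limits of the measurement. SOD2, the mitochondrial superoxide dismutase, rose by at least 3.53 and NFKBIA, the NF-kB inhibitor, by at least 2.07, since both were saturated on both LPS arrays. The NFKBIA call ended without resting replicate 1 (adjusted p = 0.0513) or resting replicate 2 (0.0523). IL6, encoding interleukin-6, had an intensity of 3.00 in resting and 12.9 in LPS cells and passed (2.08 ± 0.28, 0.0128), but not with an offset of 50 (0.25, 0.121) or without resting replicate 1 (0.105) or 2 (0.0966). MAP3K7, which encodes the kinase TAK1, differed by 0.51 ± 0.31 (0.451) and the receptor gene TLR4 by 0.37 ± 0.27 (0.547). PADI1, a peptidylarginine deiminase gene, was listed at 0 on both LPS arrays against 293 ± 14.8 in resting cells. Its other probe read a mean of 3.99 in resting and 6.45 in LPS cells, a log2 difference of 0.71 that did not pass (adjusted p = 0.354). The circadian gene PER3 read 152 in resting and 2.0 in LPS cells, and WNT11, a WNT ligand gene, 113 and 1.04. LRRC20 read 102 and 4.05, SERHL2 108 and 6.13, NIM1K 201 and 19.0 and the noncoding LINC00273 43.0 and 2.0. Folds were not given for these 7 genes because LPS values were low or near 0. The NIM1K call ended without resting replicate 1 (0.170) or 2 (0.180) or either LC53 plus LPS array (0.0801), and under quantile normalization (0.0539) and cyclic loess (0.0533). That of LINC00273 ended with an offset of 50 (0.160) and without resting replicate 1 (0.178) or 2 (0.197) or LPS replicate 1 (0.130) or 2 (0.109), and that of SERHL2 without resting replicate 1 (0.0619) or 2 (0.0581). STEAP4, encoding a metalloreductase, rose from 7.51 to 2857 and IGFBP3, a binding protein of insulin-like growth factors, from 188 to 32048.

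With limma, 2069 probes changed, 1276 higher and 793 lower with LPS, and these held 812 raised and 563 lowered genes. Quantile normalization called 5157 probes (2553 higher, 2604 lower), which included 2040 of the 2069 in the same direction, so the share of higher probes moved from 61.7% to 49.5%. Without LPS replicate 2 the split turned to 981 higher and 1598 lower (38.0% higher), and without LPS replicate 1 it was 1453 and 493. Without resting replicate 1 or 2 the count was 479 or 539, and without either LC53 plus LPS array it was 1200. Of 93 named genes that passed, 51 passed without each of the 6 arrays in turn. Calls ended for 41 and 35 genes without resting replicate 1 and 2 (adjusted p up to 0.387 and 0.365), for 7 without either LPS array (up to 0.130 and 0.109) and for 10 without either LC53 plus LPS array (up to 0.132). The direction was kept in each case. A gene whose arrays do not overlap between groups must keep it when 1 array is left out. This was thus largely fixed by the choice of called genes, here and for LC53 plus LPS against LPS.

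**Figure D1:**
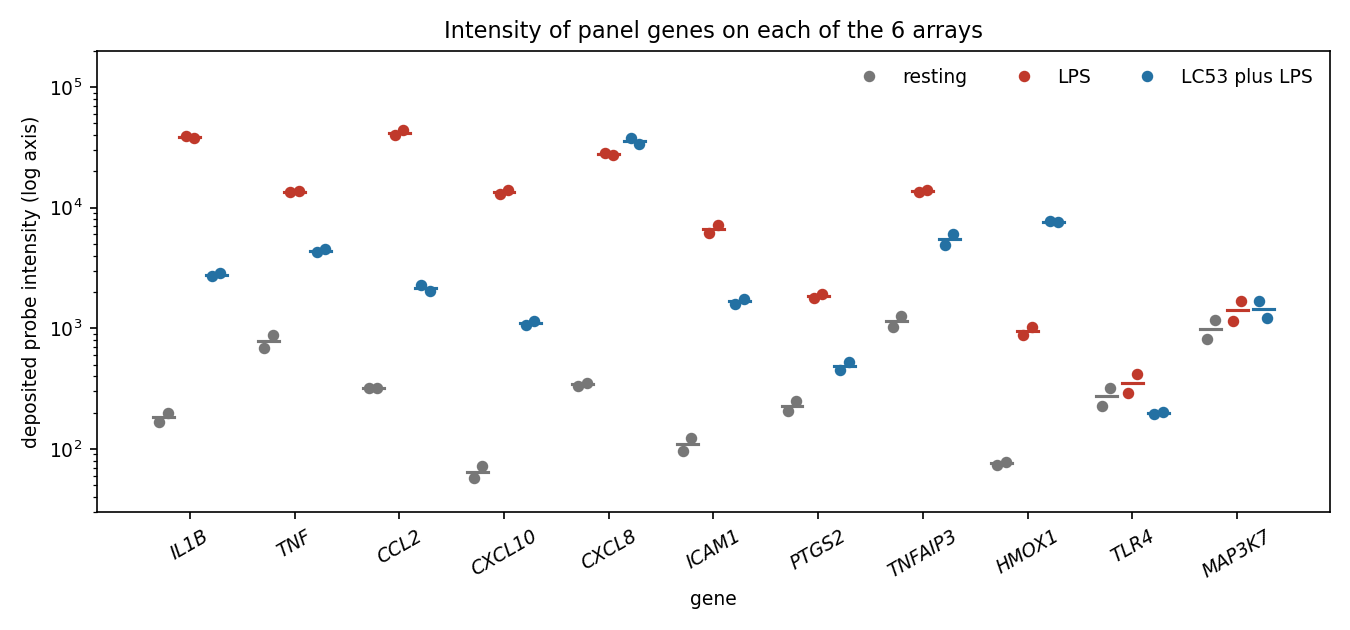
Probe intensity, on a log axis, of 11 of the 14 panel genes. Points are single arrays and horizontal bars are group means (n = 2). LC53 plus LPS values lie below LPS values for IL1B, TNF, CCL2 and CXCL10, and above them for HMOX1, and the group means of CXCL8 differed by 0.35 log2.

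The comparison of LC53 plus LPS with LPS asked which genes the compound changed in stimulated cells, the question the design was built for. Of 54 interferon-stimulated genes 46 fell, of 27 chemokines 13 fell, and of 31 targets of NRF2, a transcription factor of the oxidative and electrophile stress response, 11 rose. Each list passed camera with a preset correlation, at adjusted p of 3.42e-58, 5.76e-11 and 3.27e-11, and none with an estimated correlation (adjusted p = 0.631 for each). IL1B fell from 38698 ± 1347 to 2781 ± 119.7 (n = 2 each), a log2 difference of -3.80 ± 0.19 (adjusted p = 0.00218). CCL2 fell from 42005 ± 3127 to 2166 ± 200.4, a difference of -4.28 ± 0.18 (0.00189), and IL23A from 35169 ± 6447 to 1891 ± 300.0, a difference of -4.21 ± 0.22 (0.00218). HMOX1 (probe PH_hs_0011943) rose from 953 ± 93.9 to 7677 ± 49.5, a difference of 3.01 ± 0.18 (0.00314).

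Of 54 interferon-stimulated genes, 46 fell and 0 rose, and 53 fell and 1 rose when adjusted over the list alone, with a median log2 difference of -2.36. IFI44L fell from 8808 ± 348 to 334 ± 9.69, IDO1 from 5442 ± 121 to 116 ± 19.1, and LAMP3, a lysosomal membrane protein gene of activated dendritic cells, from 4969 ± 577 to 163 ± 32.5. RSAD2, which encodes the antiviral protein viperin, read 322 ± 158 with LPS and 0.558 ± 0.789 with LC53 plus LPS, too near 0 for a fold. The camera adjusted p of the list was 3.42e-58 (adjusted p = 0.631 with an estimated correlation) and the fry adjusted p 0.0108. After quantile normalization, median centring and cyclic loess the median was -2.41, -2.49 and -2.46.

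Of 27 chemokines 13 fell and 0 rose (15 and 2 adjusted over the list alone), with camera adjusted p = 5.76e-11. CXCL10 fell from 13599.7 ± 735 to 1112 ± 69.1, a difference of -3.61 ± 0.20, CXCL11, another interferon-induced chemokine, from 2495 ± 669 to 119 ± 41.9 and CXCL13, a B cell attractant, from 353 ± 14.0 to 12.6 ± 1.14. CXCL8 did not pass, at 27836 ± 636 with LPS and 35614 ± 2630.4 with LC53 plus LPS, a difference of 0.35 ± 0.18 (adjusted p = 0.35). Of 33 cytokines 10 fell and 0 rose (17 and 2 adjusted over the list alone, camera 3.59e-09). IL12B read 2992 ± 139.8 with LPS and 14.4 ± 4.94 with LC53 plus LPS, a difference of -5.56 with an offset of 50. TNF fell from 13563 ± 266 to 4398 ± 190.3, a difference of -1.63 ± 0.20 (0.0202). The TNF call ended without resting replicate 1 or 2 (0.0642 each), LPS replicate 1 (0.0597), or LC53 plus LPS replicate 1 (0.144) or 2 (0.143), while the difference stayed between -1.67 and -1.58. For both lists adjusted p = 0.631 with an estimated correlation.

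Of 30 adhesion, co-stimulation and migration genes 15 fell and 1 rose (16 and 3 adjusted over the list alone, camera 1.01e-10). VCAM1 fell from 4220.4 ± 339.8 to 72.0 ± 19.8 and IL7R, the receptor chain for interleukin-7, from 8592 ± 790.4 to 458 ± 46.6. ICAM1 fell from 6658 ± 657 to 1673 ± 125, a difference of -1.99 ± 0.21 (0.0138), a call that ended without LC53 plus LPS replicate 1 (0.106) or 2 (0.105). Of 31 NF-kB subunits and feedback genes 10 fell and 0 rose (17 and 1 adjusted over the list alone, 1.26e-11). BCL2A1 fell from 1533 ± 42.1 to 61.0 ± 13.7, and IER3 differed by -2.90 and passed. TNFAIP3 fell by 1.33 (0.04), a call that ended without any single array, at 0.122 without resting replicate 1 or 2, 0.0873 and 0.0516 without LPS replicate 1 and 2, and 0.240 and 0.173 without LC53 plus LPS replicate 1 and 2. NFKBIA and the first probe of SOD2 were saturated with LPS, so a fall could not be measured there, and the second SOD2 probe read 19448 with LPS and 8993 with LC53 plus LPS (-1.09 ± 0.26, 0.104). For both lists adjusted p = 0.631 with an estimated correlation.

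Of 31 NRF2 targets 11 rose and 0 fell, and 22 rose and 1 fell when adjusted over the list alone, with a median log2 difference of 1.03, or 0.88 above the median of all probes. OSGIN1, an oxidative stress-induced growth inhibitor gene, rose from 657 ± 83.1 to 5722 ± 265, a difference of 3.13 ± 0.19 (0.00323). TRIM16L rose by 2.19 and SQSTM1, an autophagy receptor gene that NRF2 induces, by 2.03, and these calls ended without LC53 plus LPS replicate 1 (0.0653 and 0.0979) or 2 (0.0635 and 0.0906). The camera adjusted p was 3.27e-11 (adjusted p = 0.631 with an estimated correlation) and the fry adjusted p 0.0179. Of 26 heat shock genes, encoding cytosolic chaperones, 3 rose and 0 fell (10 and 0 adjusted over the list alone, camera 0.000899, adjusted p = 0.799 with an estimated correlation). They were DNAJA4 (1.46), DNAJB4 (1.33) and BAG3 (1.16), none of which passed without LC53 plus LPS replicate 1 (0.165, 0.194 and 0.216) or 2 (0.154, 0.196 and 0.294), without LPS replicate 1 (0.0615, 0.0625 and 0.0854) or without either resting array (0.0831, 0.114 and 0.150 each). The endothelin receptor gene EDNRB, in no list, rose from 294 ± 44.2 to 2527 ± 171, a difference of 3.11 ± 0.20. PADI1, in no list, was listed at 0 with LPS and read 319.6 with LC53 plus LPS on the probe used here. Its other probe read 6.45 with LPS and 5.40 with LC53 plus LPS and did not pass (-0.25, adjusted p = 0.725). Among other genes in no list with a group near 0, the apoptosis repressor gene NOL3 read 1.48 with LPS and 133 with LC53 plus LPS. In the same order PER3 read 2.0 and 112, SERHL2 6.13 and 68.1, and SPRR1A 3.04 and 32.6. The growth factor receptor gene PDGFRB read 125 and 1.46, and JAML, a junctional adhesion molecule gene, 177 and 5.61. The NOL3 call ended without LPS replicate 1 (0.0873) or LC53 plus LPS replicate 1 (0.0996) or 2 (0.110), that of SERHL2 without either resting array (0.0704) or LC53 plus LPS replicate 1 (0.169) or 2 (0.142), and that of SPRR1A without LC53 plus LPS replicate 1 (0.0796) or 2 (0.0984). CCN2, a matricellular growth factor gene, fell from 871 ± 218 to 20.8 ± 2.60.

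In coagulation, plasminogen and proteases 6 of 29 genes fell and 1 rose (9 and 2 adjusted over the list alone, camera 3.7e-06, adjusted p = 0.699 with an estimated correlation). MMP1 fell from 464 ± 98.9 to 21.3 ± 4.55. In MHC class I and the immunoproteasome 2 of 18 fell and 0 rose (5 and 0, 0.000336, adjusted p = 0.699 with an estimated correlation). Among inflammasome and pyroptosis genes 4 of 21 fell and 2 rose (9 and 3, 0.00288), and among cell cycle genes 1 of 42, the cyclin D1 gene CCND1, fell (1 and 0, 0.000899), with adjusted p = 0.799 with an estimated correlation for both. The CCND1 call ended without resting replicate 1 or 2 (0.0738 each) or LC53 plus LPS replicate 1 (0.131) or 2 (0.154). In monocyte and macrophage identity 4 of 30 fell and 0 rose (9 and 4, 0.00378), and in oxidative phosphorylation 0 of 36 passed in either count while the median was 0.30 (0.00378), with adjusted p = 0.804 with an estimated correlation for both. In the AP-1 list 1 of 31, the phosphatase gene DUSP2, fell (4 fell and 2 rose adjusted over the list alone, 0.0192, adjusted p = 0.836 with an estimated correlation). The DUSP2 call ended without resting replicate 1 or 2 (0.150 each), LPS replicate 1 (0.0615), or LC53 plus LPS replicate 1 (0.177) or 2 (0.279). The oxidative phosphorylation call ended under quantile normalization (0.0994), cyclic loess (0.0933) and without LPS replicate 2 (0.0540). The AP-1 call ended without LPS replicate 1 (0.0612) or LC53 plus LPS replicate 2 (0.0516), and the monocyte call without LPS replicate 1 (0.0620).

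The other 13 lists did not pass. Members that rose and fell numbered 1 and 0 of 33 for TLR4 to IKK and MAPK signalling, 0 and 2 of 18 for prostaglandin and leukotriene synthesis, 2 and 0 of 34 for the unfolded protein list, 0 and 1 of 6 for metallothioneins, 1 and 1 of 30 for apoptosis, 0 and 2 of 22 for p53 targets and 1 and 0 of 20 for cholesterol synthesis. They were 2 and 1 of 24 for lipid efflux, 0 and 1 of 34 for glycolysis, 1 and 1 of 38 for ribosomal proteins, 0 and 2 of 14 for MHC class II, 1 and 0 of 28 for lysosome and autophagy, and 0 and 2 of 29 for other cell types, where DCN read 26.8 and LUM 88.6 with LC53 plus LPS. Neither of them passed without LC53 plus LPS replicate 1 (0.0773 and 0.114) or 2 (0.110 and 0.0906), nor LUM without either resting array (0.0567) or LPS replicate 1 (0.0573). Adjusted over the list alone the counts were 1 and 1 for TLR4, 4 and 4 for prostaglandins, 6 and 1 for unfolded protein, 0 and 1 for metallothioneins, 2 and 3 for apoptosis, 1 and 4 for p53 and 2 and 1 for cholesterol. They were 3 and 2 for lipid efflux, 0 and 1 for glycolysis, 1 and 1 for ribosomal proteins, 0 and 3 for MHC class II, 4 and 2 for lysosome and 0 and 3 for other cell types. The median was positive while the test direction was down for TLR4 (median 0.03, mean -0.02), apoptosis (0.03, -0.07), p53 (0.06, -0.11), glycolysis (0.01, 0.02) and other cell types (0.16, 0.06). MAP3K7 differed by 0.03 ± 0.31 (0.969), TLR4 by -0.80 ± 0.27 (0.212) and IL6 by -1.25 ± 0.28 (0.0933). TLR4 and IL6 passed under quantile normalization (0.0369 and 0.0229), median centring (0.0297 and 0.0133) and cyclic loess (0.0295 and 0.0194), and under no other alternative (up to 0.525 and 0.409). IL6 read 12.9 with LPS, and with an offset of 50 its difference was -0.18. PTGS2 fell by 1.92 (0.0128), a call that ended without LC53 plus LPS replicate 1 (0.0996) or 2 (0.0921).

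With limma, 834 probes changed, 218 higher and 616 lower with LC53, holding 160 raised and 408 lowered genes, and 5849 probes had an unadjusted p under 0.05. The median of all probes was 0.15 as deposited and 0.06, 0.02 and 0.01 after quantile normalization, median centring and cyclic loess. Quantile normalization called 3755 probes (1650 higher, 2105 lower), including 822 of the 834 in the same direction, and the share of higher probes moved from 26.1% to 43.9%. The count was 305 without either resting array, 530 and 2318 without LPS replicate 1 and 2, and 142 and 91 without LC53 plus LPS replicate 1 and 2. Without LPS replicate 2 the share of higher probes was 73.1%. Of 77 named genes that passed, 24 passed without each array in turn, among them IL1B, CCL2, IL23A, CXCL10, IL7R, IDO1, VCAM1, IER3, HMOX1, OSGIN1 and EDNRB. Calls ended for 30 genes without either resting array (adjusted p up to 0.184), for 22 and 4 without LPS replicate 1 and 2 (up to 0.104 and 0.0580) and for 50 without either LC53 plus LPS array (up to 0.274 and 0.320), with the direction kept in each case.

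**Figure D2:**
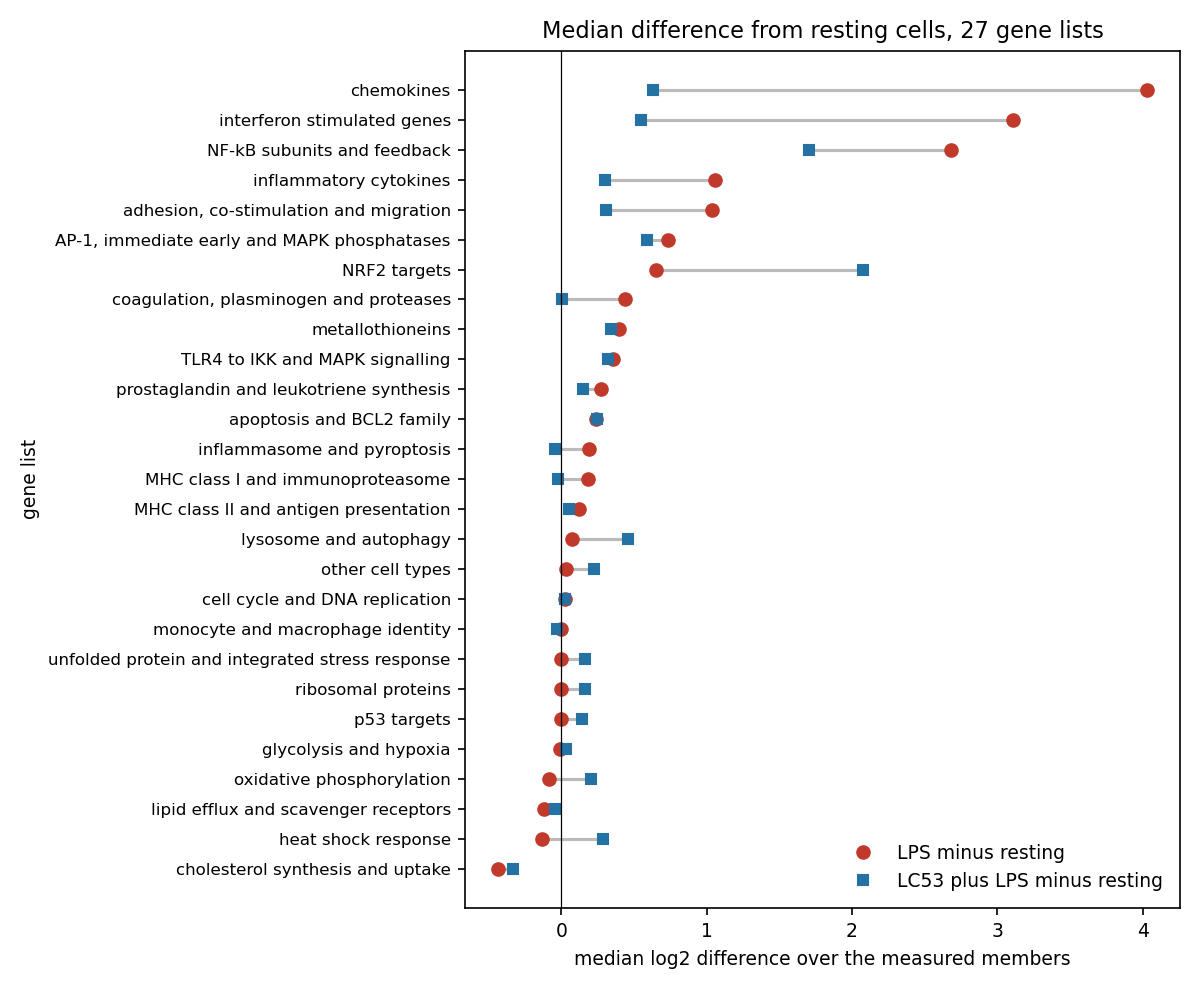
Median log2 difference from resting cells over the measured members of each of the 27 gene lists, for LPS (red circles) and LC53 plus LPS (blue squares). The median of interferon-stimulated genes lies at 3.11 with LPS and 0.55 with LC53 plus LPS, and that of NRF2 targets at 0.65 and 2.08.

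The calls of both contrasts were overlaid to ask how many genes changed by LPS were moved back by LC53. Of 812 genes raised by LPS, 328 (40.4%) fell with LC53, against 18.1 from independent calls, and 12 rose further, against 7.12. Of 563 genes lowered by LPS, 60 rose, against 4.93, and 0 fell. Both contrasts used the LPS arrays with opposite sign. In 100 simulations of unchanged groups a mean of 0.02 probes were raised and then lowered, against 485 observed. The simulated groups held no LPS response, so that count was near 0 by design. It cannot show how many truly raised probes the shared arrays would move back. In 775 genes the median share of the LPS rise that remained with LC53 was 41.2% (interquartile range 16.6% to 71.7%), and it was 46.5% and 38.3% when genes were chosen on one LPS array and measured on the other. In 496 lowered genes 62.0% of the fall remained.

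The lists were compared in how many of their raised genes fell with LC53, in tests chosen after the list results were seen. Fisher's exact test takes genes as independent, while the estimated correlation between the interferon-stimulated genes was 0.483. Its p-values may therefore overstate the evidence from 2 arrays per group. Shares remaining are of the log2 rise. Of the 50 interferon-stimulated genes raised by LPS, 46 fell with LC53, against 37.0% of the other 762 raised genes (Fisher's exact test, 2-sided, adjusted over 11 lists, p = 4.39e-14), and the median share remaining was 18.3%. Among genes raised at least 4-fold it was 42 of 42 against 57.1% (Fisher's exact test, adjusted over 8 lists, p = 4.62e-09). Without LC53 plus LPS replicate 1 these counts were 17 of 49 (0.000593) and 17 of 42 (0.00801), and without replicate 2 they were 10 of 49 and 10 of 42 and did not pass (0.0541 and 0.272). Of 18 raised chemokines 13 fell (adjusted p = 0.0191), with a median share remaining of 30.2%, and of 14 adhesion genes 12 (0.00338), with 52.2% remaining, above the 41.2% of all raised genes. Neither passed among genes raised at least 4-fold, where 13 of 17 chemokines fell against 61.5% of the others (0.350) and 11 of 12 adhesion genes against 61.2% (0.0697). The chemokine call ended without resting replicate 1 (0.136) or 2 (0.0840) or LPS replicate 2 (0.105) and under quantile normalization (0.0671), median centring (0.103) and cyclic loess (0.0659). The adhesion call ended without resting replicate 1 (0.654) or 2 (0.511), LPS replicate 1 (0.0746) or 2 (0.0681), or LC53 plus LPS replicate 1 (0.259) or 2 (0.732). Of 15 cytokines 10 fell (0.109), with 34.5% remaining, which passed under quantile normalization (0.0114), median centring (0.0257) and cyclic loess (0.00348) and without LC53 plus LPS replicate 1 (0.00399) or 2 (0.0321). Of 20 NF-kB genes raised at least 4-fold, 9 fell against 63.2% of the others (Fisher's exact test, adjusted over 8 lists, p = 0.203). Of the 25 raised NF-kB genes 2 were saturated, so their fall could not be measured. Of the other 23, 10 fell against 40.4% of the unsaturated genes outside the list (adjusted p = 1), with 69.1% remaining. With all 25 the adjusted p was also 1, and without resting replicate 1 it was 0.0124, where 2 of 16 fell against 50.4%. Of 12 raised AP-1 genes 1 fell (0.0737, and 0.0407 without LPS replicate 2), with 85.1% remaining. Of 11 raised NRF2 targets 0 fell (0.0146) and 6 rose further (1.16e-08). The first of these calls ended without resting replicate 1 (0.136) or 2 (0.109), LPS replicate 1 (0.149), or LC53 plus LPS replicate 1 (0.424) or 2 (0.732), and the second without resting replicate 1 (0.130) or 2 (0.253). The share remaining in prostaglandin, coagulation, apoptosis and p53 genes was 49.5%, 28.7%, 70% and 45.7%, with 2 of 5, 4 of 7, 1 of 7 and 2 of 5 raised genes lowered (1, 0.618, 0.395 and 1). The 568 probes moved back became 1998 under quantile normalization. They became 191 and 207 without resting replicate 1 and 2, 1064 without LPS replicate 2, and 115 and 76 without LC53 plus LPS replicate 1 and 2.

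**Figure D3:**
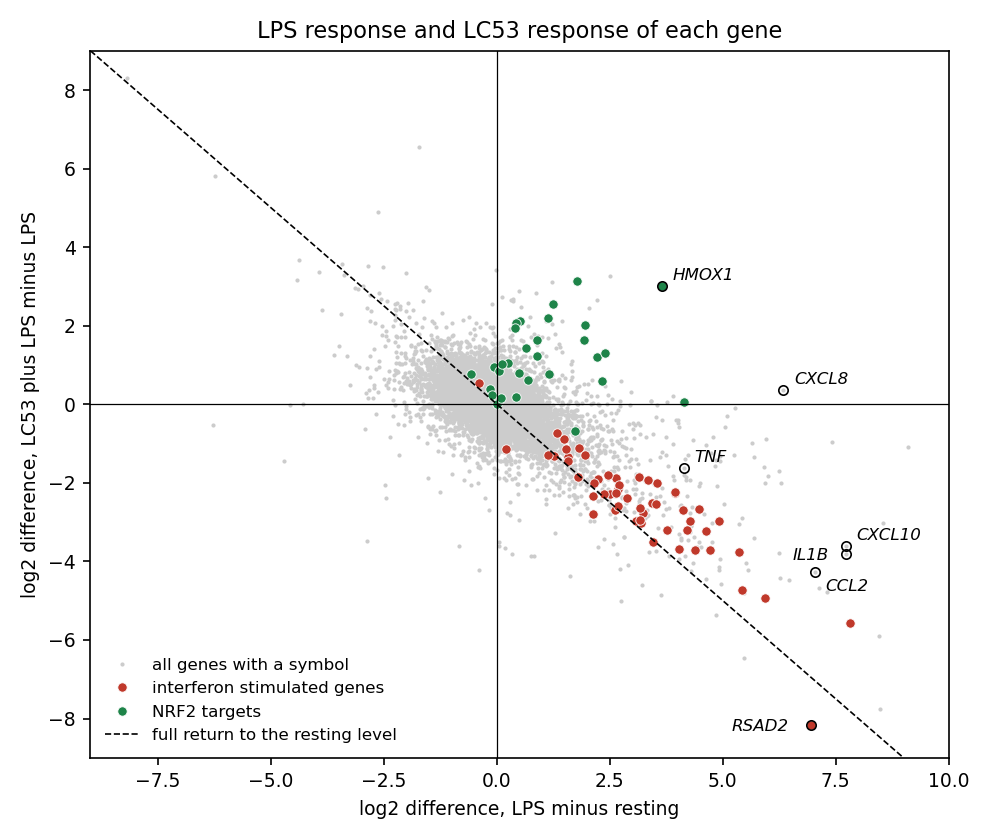
Log2 difference between LC53 plus LPS and LPS against the log2 difference between LPS and resting cells, with 1 point per gene. Points on the dashed line returned to the resting level. Of 54 interferon-stimulated genes (red) 46 fell with LC53, and of 31 NRF2 targets (green) 11 rose.

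The comparison of LC53 plus LPS with resting cells asked how far stimulated cells with the compound lay from resting cells. Of 31 NRF2 targets 19 and of 31 NF-kB genes 21 were higher than in resting cells (camera adjusted p = 1.34e-22 and 2.42e-22, adjusted p = 0.601 with an estimated correlation for both), and 47 of 54 interferon-stimulated genes did not pass the test. HMOX1 was higher, at 7677 ± 49.5 against 76.0 ± 3.74 (n = 2 each), a log2 difference of 6.66 ± 0.18 (adjusted p = 0.000763), and CXCL8 by 6.69 ± 0.18 (0.000763). TNFAIP6 was higher by 8.02, or 6.45 with an offset of 50, and IGFBP3 by 6.45. IL1B was higher by 3.93, CXCL10 by 4.11 and ICAM1 by 3.93, or 3.61, 3.34 and 3.43 with an offset of 50. The stem cell factor receptor gene KIT was lower, at 150.3 ± 3.68 against 3321 ± 224, a difference of -4.46 ± 0.18, and SERPINB2 by -4.60 ± 0.19. WNT11 was listed at 0 on both LC53 plus LPS arrays and LRRC20 read 1.46, against 113 and 102 in resting cells.

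Of 31 NRF2 targets 19 were higher and 0 lower (25 and 0 adjusted over the list alone), with a median of 2.08 (camera adjusted p = 1.34e-22). Of 31 NF-kB genes 21 were higher and 0 lower (26 and 0), with a median of 1.70 (2.42e-22). For both adjusted p = 0.601 with an estimated correlation. Of 27 chemokines 7 were higher (13 adjusted over the list alone, 2.55e-09) and of 54 interferon-stimulated genes 7 (23 higher and 2 lower adjusted over the list alone, median 0.55, 2.35e-07). Of 31 AP-1 genes 9 were higher (15 and 3, 0.000123), of 30 adhesion genes 10 were higher and 3 lower (12 and 6, 0.0234), of 33 TLR4 pathway genes 3 and 1 (10 and 1, 0.0348), of 26 heat shock genes 1 (1 and 0, 0.0234) and of 28 lysosome genes 4 (5 and 1, 0.0213). Of 20 cholesterol genes 1 was lower (1 higher and 3 lower, 0.00092). For these 8 lists adjusted p = 0.960 with an estimated correlation. Calls ended for the TLR4 list without resting replicate 1 (0.166) or 2 (0.0682), either LPS array (0.0791) or LC53 plus LPS replicate 1 (0.135), and with median centring (0.109), only the 4 arrays compared (0.0791), the replicate block (0.0601) and the mean of a gene's probes (0.0807). They ended for adhesion without either LPS array (0.0795), with only the 4 arrays compared (0.0795), the replicate block (0.0601), array weights (0.0529) and an offset of 50 (0.0765), for heat shock without resting replicate 2 (0.0785) or LC53 plus LPS replicate 1 (0.139), and for lysosome without the same arrays (0.0682 and 0.0507). Among the 17 lists that did not pass, median, mean and test direction differed in sign for inflammasome (-0.04, 0.12, down), coagulation (0.01, 0.06, down), cell cycle (0.03, -0.02, down), lipid efflux (-0.04, 0.03, down), glycolysis (0.03, 0.20, down) and MHC class II (0.05, 0.08, down).

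With limma, 941 probes differed, 557 higher and 384 lower, in 370 and 273 genes. The median of all probes was 0.11 as deposited and 0.01 after quantile normalization, which called 3494 probes (1519 higher, 1975 lower) and kept 932 of the 941, so the share of higher probes moved from 59.2% to 43.5%. The count was 75 and 93 without resting replicate 1 and 2, 1555 without either LPS array and 100 without either LC53 plus LPS array. CCL2 was higher by 2.75, TNF by 2.51, TNFAIP3 by 2.27 and NFKBIA by at least 2.08, and PTGS2 (1.10, 0.0549), IL6 (0.83, 0.225), MAP3K7 (0.55, 0.466) and TLR4 (-0.43, 0.520) did not pass. PTGS2 passed in 8 of 18 alternatives (adjusted p from 0.00225 to 0.463), which were quantile normalization (0.0212), median centring (0.0337), cyclic loess (0.0224), leaving out the dimmest quartile of probes (0.0217) or those below the median brightness (0.00571), a variance trend (0.00225), array weights (0.0164) and an offset of 50 (0.0195). The CCL2, TNF, TNFAIP3 and NFKBIA calls ended without resting replicate 1 (0.0584, 0.0806, 0.107 and 0.109) or 2 (0.0540, 0.0531, 0.0711 and 0.105). Those of TNF, TNFAIP3 and NFKBIA ended without LC53 plus LPS replicate 1 (0.0607, 0.0629 and 0.0639) or 2 (0.0601, 0.0785 and 0.0819). In no contrast did any list pass camera with an estimated correlation (0 of 27), against 13, 14 and 10 with the preset correlation and 8, 6 and 4 with fry. The estimated correlation is imprecise with 2 arrays per group.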

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

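The test without saturated probes was chosen after the data had been seen, and the others before. Of 198 results for named genes, 193 kept direction and side of the threshold with quantile normalization, 192 with median centring and 192 with cyclic loess, 197 with a variance trend, 191 with an offset of 50 and 193 with the mean of a gene's probes, and 192 of 192 without saturated probes. They were 158 with only the 4 arrays compared, 164 with the replicate block and 150 with array weights, and from 123 to 186 with 1 array left out. Of 37 list results called, 35 were kept under each scaling and from 30 to 36 with 1 array left out, and 0 reversed. The number of lists called stayed within 1.5 times under each alternative.

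Probe counts for LPS against resting, LC53 plus LPS against LPS, and LC53 plus LPS against resting, and then the count moved back, were 5157, 3755, 3494 and 1998 with quantile normalization, 3802, 2416, 2440 and 1348 with median centring, 5032, 3585, 3370 and 1968 with cyclic loess, 3177, 2144, 2155 and 1183 without the probes below the median brightness, 3998, 2880, 2761 and 1572 with a variance trend, 3382, 2214, 2093 and 1316 with an offset of 50, 1200, 305, 1555 and 244 with only the 4 arrays compared, and 1267, 264, 3234 and 216 with array weights. Without the dimmest quartile the last 3 counts were 1500, 1628 and 900, and with the replicate block 389, 481 and 310. Arrays with the same replicate number share only that number, and the deviations of their probes from the group means correlated at 0.0581, -0.0769 and 0.201 between groups. With adjusted p under 0.01 the 3 probe counts were 763, 180 and 224, and with unadjusted p under 0.05 and at least 2-fold the last 2 were 1904 and 1912. The cause was not tested, except that stricter thresholds lower the counts. Fewer arrays leave fewer degrees of freedom, but this does not account for every move. The LC53 plus LPS against resting count rose from 941 to 1555 with only the 4 arrays compared.

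With 1 array left out the counts ranged from 479 to 2579, from 91 to 2318 and from 75 to 1555, and the count moved back from 76 to 1064. A group then has 1 array, which is assumed to vary like the other groups. The median share of the log2 LPS rise remaining was 34.4% with median centring and 34.6% with cyclic loess, against 41.2%. For LC53 plus LPS against LPS, 3 genes that passed under no setting changed sign. NFKBIA was -0.038 with quantile normalization, -0.12 with median centring, -0.23 with cyclic loess and from -0.14 to 0.16 with 1 array left out. MAP3K7 was -0.092 with median centring, -0.040 with cyclic loess and from -0.24 to 0.31 with 1 array left out, and SOD2 from -0.14 to 0.087. NFKBIA and SOD2 were saturated on both LPS arrays, so their values follow the scaling of the arrays and measure no change. Low signal limited dim probes, whose replicates differed with an SD of 0.639 to 0.747 on the log2 scale under log2 4, against 0.161 to 0.240 over log2 12.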

Other observations

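The tests of general stress, of the CXCL8 reading against the saturation level, of the brightness of LPS replicate 2 and of genes beyond both groups were chosen after the results were seen, as were the genes named in this paragraph and in the next other than KIT, PSAT1, ASNS and PLIN2. In LC53 plus LPS cells 49 genes were lower than in both resting and LPS cells, and the count was 3 without either resting array, 37 and 61 without LPS replicate 1 and 2, and 11 and 4 without LC53 plus LPS replicate 1 and 2. KIT read 3321 in resting, 1842 in LPS and 150.3 in LC53 plus LPS cells (adjusted p = 0.00218 against LPS and 0.00124 against resting), and passed both tests without each array in turn. IL1RN, encoding the interleukin-1 receptor antagonist, and FGL2, a fibrinogen-like protein gene, read 2786 and 410.4 in resting, 14491 and 2702 in LPS, and 1348 and 150.03 in LC53 plus LPS cells. Against resting their adjusted p was 0.0397 and 0.0358, and these calls ended without resting replicate 1 (0.367 and 0.197) or 2 (0.378 and 0.300) or LC53 plus LPS replicate 1 (0.254 and 0.222) or 2 (0.252 and 0.132). Higher than in both groups were 64 genes. Of these, 11 were NRF2 targets, which were all the targets that rose against LPS, and LPS lowered 0 of the 31. The exact test thus largely repeats that comparison. It set 11 of 31 NRF2 targets against 53 of 18224 other genes that were higher than in both groups (Fisher's exact test, 2-sided, with genes taken as independent, p = 3.19e-20). Without resting replicate 1 and 2 there were 8 and 10 such genes, of which 4 and 4 were NRF2 targets, without LPS replicate 1 and 2 there were 28 and 158 (6 and 14), and without LC53 plus LPS replicate 1 and 2 there were 3 and 5 (2 and 2), with p up to 2.78e-05 in the same exact test.

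Among CXC chemokines for neutrophils, CXCL2 read 1776 with LPS and 1655 with LC53 plus LPS (-0.08, adjusted p = 0.894), CXCL3 303 and 357 (0.23, 0.560) and CXCL1 23224 and 12647 (-0.87, 0.101). PSAT1, a serine synthesis enzyme gene, fell with LPS from 11634 to 3684 (-1.66, 0.00561) and rose with LC53 to 14278 (1.95, 0.00751), and ASNS, encoding asparagine synthetase, read 3777, 2541 and 6381, a difference of -0.57 with LPS that did not pass (0.128) and a rise of 1.33 with LC53 (0.0217). The LPS call of PSAT1 ended without resting replicate 1 (0.0896) or 2 (0.0740), and its LC53 call without LC53 plus LPS replicate 1 (0.0773) or 2 (0.0845). The ASNS call ended without LC53 plus LPS replicate 1 (0.160) or 2 (0.180) or either resting array (0.103). PLIN2, a lipid droplet coat protein gene, read 7336, 6828 and 24116, a rise of 1.82 with LC53 (0.0129) that did not pass without LC53 plus LPS replicate 1 (0.0920) or 2 (0.121).

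Of 31 NRF2 targets 11 rose and 0 fell with LC53 plus LPS against LPS (camera adjusted p = 3.27e-11, adjusted p = 0.631 with an estimated correlation). The scaling of the arrays was argued against, since the list's median was 0.83 after quantile normalization. A rise of all genes of like brightness was argued against too, since the median of 1.03 lay at percentile 100 of 10000 random lists matched on intensity, whose highest was 0.44. General stress stays open and cannot be told apart, since the heat shock median reached 0.395 of the NRF2 median, each less the median of all probes, between the bounds set for either reading. A candidate explanation is that LC53 engages the NRF2 pathway in LPS-treated cells. The design could not test it, since only RNA was measured and NRF2 itself was not altered in any group. Cells given LC53 alone were not listed either.

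CXCL8 did not pass the test with LC53 (0.35, adjusted p = 0.35) while IL1B, CCL2 and IL23A fell. Scaling was argued against, since the CXCL8 difference was 0.12 after quantile normalization. Scanner saturation was argued against too, since the highest CXCL8 reading was 63.2% of the saturation level and 7 of 17 brighter unsaturated probes raised by LPS fell. The share of other raised probes of like brightness that stayed within 1 log2 of their LPS level, 64.2% (34 of 53) against 47.7% of all raised unsaturated probes, lay between the bounds set for either reading. No biological explanation was tested.

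Of 812 genes raised by LPS, 328 fell with LC53, 12 rose further and 472 did not pass. Independent noise in the LPS arrays shared by both contrasts was argued against as the whole cause. The covariance of the log2 differences was -0.292, below the lowest of 100 simulated values of -0.0615. The simulated noise followed the spread within groups and was drawn separately for each probe. An error common to both LPS arrays or to many probes was therefore not covered. The brightness of LPS replicate 2 was argued against as well, since 43.5% of the log2 rise remained without that array, against 41.2%. The brightness of LPS replicate 1 cannot be told apart by leaving it out, since leaving out the dimmer LPS array (38.1%) could only lower the share. After median centring, quantile normalization and cyclic loess, which bring the arrays to a like brightness, 34.4%, 36.4% and 34.6% of the log2 rise remained. These values argue against array brightness as the cause in the genes raised by LPS. A candidate explanation is that LC53 dampens part of the LPS response, with the spread between cultures unknown because the labels do not say whether replicates were separate cultures.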
